A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

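The series compared 2 strains of the budding yeast Saccharomyces cerevisiae, a wild type and a strain labelled GCN2c, on 2-colour spotted arrays with 1 spot value per open reading frame. GCN2 encodes the protein kinase that phosphorylates the translation factor eIF2 when uncharged tRNA accumulates. Per the series' design text, GCN2c is an overexpressing strain and 4 biological replicates were hybridised for a one-class test. The sample labels call GCN2c a mutant strain. Per the labels' protocols, cells grew in rich medium (YPD) at 28 °C in 50 mL cultures to an absorbance (Ab660) of 0.6, and 30 µg of total RNA was copied into amino-allyl cDNA and coupled to Cy3 or Cy5. GCN2c RNA was in Cy5 on replicates 1 and 3 and in Cy3 on replicates 2 and 4.

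The values used here were the deposited log2 ratios of the series' value table, 6211 open reading frames on 4 arrays, made by the authors. Per the labels' protocols, the authors flagged spots with visible defects or with a signal under 2 times the local background in either channel. The scanner, the background correction, the centring and the direction of the ratios were not given in the sources used here, and scanner files were not used here. The log base is likely 2 but is not stated. A 16-bit scanner bounds a log2 ratio at 16, and a natural or base-10 log ratio at less. Each array held values beyond even that bound, so those values are implausible as spot ratios and are no proof of the base. The medians of the 4 arrays were -0.03, -0.09, -0.05 and -0.09 for replicates 1 to 4, so each array was close to centred at 0 as deposited, and no further centring was applied. The arrays held values for 6177, 6137, 6057 and 6138 open reading frames. All 4 arrays had a value for 5995 of them, 3 arrays for 135, 2 for 49, 1 for 26 and none for 6. Values beyond 16 numbered 3, 1, 6 and 1. No spot intensity was used here, so signal over background was not judged. The number of arrays, the unequal dye balance and such implausible values all limit the precision. On each array more genes also lay within 0.005 of 1 shared ratio, -0.23, 0.25, 0.22 and 0.26 on replicates 1 to 4, than at neighbouring values. They numbered 69, 50, 57 and 51, against 46.3, 32.5, 35.5 and 32.2 at neighbouring values, so most genes at the shared ratio may lie there by chance. Saturated spots could give the excess, but saturation could not be checked without intensities. On at least 2 of the 3 replicates, 14 genes lay at the shared ratio, 6 of them glycolytic.

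Open reading frame names were matched to locus tags of the yeast R64 gene table for gene symbols. Of the 6211 names, 5639 matched exactly and 5662 matched when case was ignored, and 549 had no match and kept the name in the table. Each open reading frame had 1 row, so no averaging over spots was needed. No genome build is named with the ratios, so no coordinates are given.

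Direction followed a rule set before the data were examined. Over the 4 pairs of arrays of opposite dye orientation the median Pearson correlation across genes, as deposited, was 0.237. A value above 0 was read as ratios already turned by the authors to one direction on every array. The correlation bears only on that: it would be the same for wild type over GCN2c, and a dye effect shared by ratios not turned could also raise it. GCN2c over wild type was assumed, since GCN2c was in Cy5 on replicates 1 and 3 and ratios are usually Cy5 over Cy3. The sample titles read WT vs GCN2, with wild type first, but do not say which strain is the numerator. No label states the direction, so it is not settled. Turning every array would swap higher and lower throughout.

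Replicates 2 and 4 held nearly the same values. Across 6136 genes the difference between them lay within 0.002 log2 of a constant 0.004 for 95.1% of genes and within 0.01 for 97.46%. The SD of these differences was 0.0638, against 0.852 between replicates 1 and 3, which share the other dye orientation. Replicates 2 and 4 were therefore averaged and counted as 1 replicate. This departs from the planned fit of 4 arrays and leaves 3 independent replicates, 2 with GCN2c in Cy5 and 1 with GCN2c in Cy3. The fit of the 4 columns as 4 replicates is kept as an alternative. Dye and strain effects are unequally balanced in a mean over 3 such replicates.

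Each gene with values on at least 3 of the 4 arrays was tested, 6130 in all, and a gene missing on replicate 1 or 3 then rests on 2 values. The mean log2 ratio was tested against 0 with limma 3.58.1 in R 4.3.3 (intercept only, empirical Bayes, two-sided). P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. A complete gene had 2 residual degrees of freedom and the prior added 3.37. The SD beside a value is the spread over the 3 replicates. "Rose" and "fell" are used for genes past the adjusted threshold.

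A set of 34 gene lists (amino acid and purine pathways, Gcn4 targets, translation, cell cycle, DNA replication and repair, stress, metabolism, regulons, and markers of mating type, sporulation and strain auxotrophy) was fixed before the data were examined. Each list with at least 5 tested genes was set against all other genes with limma's cameraPR on the moderated statistics, at a preset inter-gene correlation of 0.01, and adjusted over the 34 lists. camera with a correlation estimated per list, and fry, were run on the 5997 genes with values on all 3 replicates. With 2 residual degrees of freedom, the camera test with estimated correlation has little power. For each list the median over members was also taken per replicate and averaged over the 3 replicates. An exact two-sided sign-flip test of those medians has 8 sign patterns, and its smallest possible p is 0.25.

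Named genes were chosen by a rule set before the data were examined. They were GCN2 and GCN4, the 10 largest changes in each direction past the threshold with one sign on every replicate, and the 3 smallest p-values of each list past its threshold. To these came the 2 smallest p-values of the Gcn4 target, G1/S, DNA replication and DNA damage lists. Other genes are named only where a list count is small or as stated. One gene that the rule selects is not reported here.

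The procedure was tested on simulated ratios for the same 6130 genes and 3 replicates, with 200 genes changed, in 20 draws. It recovered 0.20% of genes changed by 1.5-fold, 13.9% at 2-fold, 63.3% at 4-fold and 84.7% at 8-fold. Of the calls, 3.34% were false, and there were 0.15 false list calls per draw. The simulated genes varied independently and no dye effect was drawn. These false rates therefore do not cover genes that vary together or a dye effect shared by arrays. Changes of 2-fold or less are mostly missed gene by gene at this number of arrays.

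The alternatives tried were centring, scaling, other filters on missing values, a dye term, a robust variance prior, replicates 2 and 4 turned, each replicate left out, other thresholds, a plain t-test and one-class SAM. Without replicates 2 and 4, only replicates 1 and 3 remain, both with GCN2c in Cy5. Dye and strain effects cannot be told apart in that fit, which holds for every value given without replicates 2 and 4. Treating the 4 columns as 4 replicates, SAM on 3 replicates, setting values beyond 16 or at the shared ratio to missing and keeping only names matched to the R64 table were added after the data were examined. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 prepared the values, and matplotlib 3.10.9 drew the plots.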

Results

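Relative mRNA levels were measured in yeast cells labelled GCN2c against wild-type cells, both growing in rich medium, on 4 arrays. Replicates 2 and 4 differed by far less than replicates 1 and 3 did (SD of the gene differences 0.0638 against 0.852) and were counted as 1 sample, so n = 3 unless stated, 2 with GCN2c in Cy5 and 1 in Cy3. Across genes, replicates 1 and 3, with GCN2c in Cy5, correlated at Pearson r = 0.449 and Spearman rho = 0.564. The hybridisation of replicate 2, with GCN2c in Cy3, correlated with replicate 1 at r = 0.183 and with replicate 3 at r = 0.294. Genes are not independent replicates, so these correlations carry no p-value. Ratios are read as log2 of GCN2c over wild type. No label states this direction or the log base, and turning every array would swap higher and lower throughout. The series title places the comparison in work on Gcn2 and a G1/S checkpoint after DNA damage, and no treatment is named for these cultures.

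**Figure D1:**
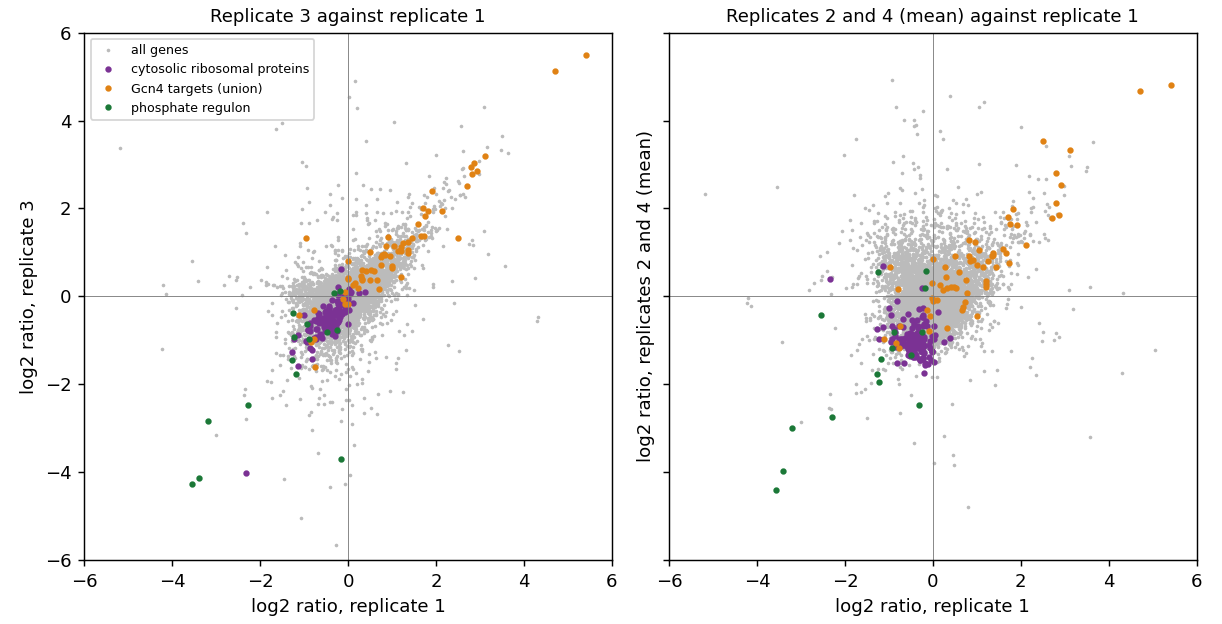
Log2 ratios of GCN2c over wild type per gene, replicate 3 (left) and the mean of replicates 2 and 4 (right) against replicate 1, with 3 gene lists in colour; 5 genes on the left and 6 on the right lie beyond the plotted range of 6 log2 units. Correlation across genes was 0.449 on the left, and lower on the right, where the dye orientation was opposite.

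The gene the strain is named for showed no change past the threshold. GCN2 had a log2 ratio of -0.33 ± 0.39 (SD, n = 3; limma adjusted p = 0.453), with values of -0.39 and 0.10 on replicates 1 and 3 and -0.68 on replicates 2 and 4. With replicates 2 and 4 turned the other way the GCN2 log2 ratio was 0.13 (adjusted p = 0.964), and with every array turned it would be 0.33, so no reading put it past the threshold. The overexpression that the design text names was thus not seen at this spot. The sample labels call GCN2c a mutant strain. The sources used here do not say whether GCN2c is an altered allele or a copy that the spot would not measure. It is therefore called the strain labelled GCN2c. GCN4, the transcription activator whose translation Gcn2 promotes, stood at 0.59 ± 0.23 (SD, n = 3; limma adjusted p = 0.180) and was positive on every replicate.

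Of 6130 genes tested, 106 rose and 20 fell in the strain labelled GCN2c, and each of these 126 had one sign on every replicate. The largest increases were in SNZ1, a vitamin B6 synthesis gene, at 5.23 ± 0.37 (SD, n = 3; limma adjusted p = 0.0033) and in ARG1, argininosuccinate synthetase, at 4.83 ± 0.25 (adjusted p = 0.0033). STR3, a cystathionine beta-lyase of methionine synthesis, rose by 3.53 ± 0.67, and the arginine gene ARG4 by 3.22 ± 0.11. Genes of the cell surface were also among the 10 largest. GSC2, an alternative catalytic subunit of beta-1,3-glucan synthase, rose by 3.47 ± 0.19, the cell-surface aspartic protease gene YPS3 by 3.36 ± 0.37, and the cell wall protein gene NCW2 by 3.23 ± 0.33. MSS11, a transcription factor of filamentous growth, rose by 3.17 ± 0.22, FMP33 by 3.03 ± 0.72, and HES1, an oxysterol-binding protein gene, by 2.97 ± 0.42 (adjusted p between 0.0052 and 0.0193 for these).

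The largest decreases were in the acid phosphatase genes PHO12, at -4.07 ± 0.45 (SD, n = 3; limma adjusted p = 0.0052), and PHO11, at -3.83 ± 0.38 (adjusted p = 0.0052). These genes are near-identical copies whose spots can share signal. YHB1, a flavohaemoglobin that detoxifies nitric oxide, stood at -3.01 ± 0.14, and VTC3 and VTC1, of the vacuolar polyphosphate polymerase, at -3.01 ± 0.18 and -2.50 ± 0.22. The siderophore transporter gene SIT1 was at -2.56 ± 0.24, the fatty acid desaturase gene OLE1 at -2.38 ± 0.14 and the purine salvage gene HPT1 at -2.23 ± 0.11. CHA1, a serine and threonine deaminase, stood at -1.96 ± 0.37, and PLB2, a phospholipase B, at -1.95 ± 0.53. The adjusted p was between 0.0052 and 0.0223 for the others. The PLB2 call had an adjusted p of 0.0328, and of 0.0505 without replicate 3.

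The changes that passed were large, which the test itself favours: in the simulation it recovered 13.9% of genes changed by 2-fold. The 106 higher genes had a median log2 ratio of 1.78 and ranged from 1.15 to 5.23, and the 20 lower genes had a median of -1.92 and ranged from -1.33 to -4.07. The median SD between replicates over all genes was 0.34. At an unadjusted p under 0.05, 1268 genes passed. All 3 replicates shared a sign for 46.6% of the genes with 3 values, against 25% if signs were independent. Replicates 1 and 3, of one dye orientation, shared a sign for 71.6% of genes. Across orientations it was 56.4% for replicates 1 and 2 and 65.0% for replicates 2 and 3. A dye effect common to replicates 1 and 3 could thus raise the share. The count of 126 was 74 without replicate 3 and 353 without replicates 2 and 4, and it was 650 with a dye term. The 353 rest on replicates 1 and 3, both with GCN2c in Cy5, so dye and strain effects cannot be told apart there. The dye term fits replicates 2 and 4 exactly, so the spread behind the 650 is that between replicates 1 and 3 alone. The count was 1062 with the 4 columns as 4 replicates, and 0 with replicates 2 and 4 turned, where limma left 250 genes at an unadjusted p under 0.05.

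**Figure D2:**
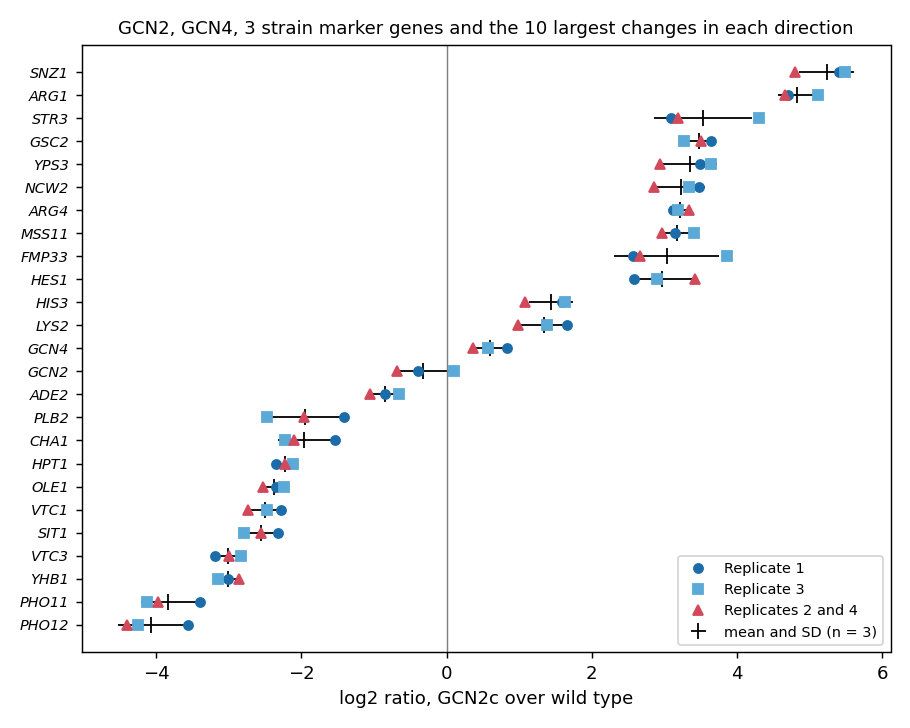
Log2 ratio of GCN2c over wild type per replicate for GCN2, GCN4, the strain marker genes HIS3, LYS2 and ADE2, and the 10 largest changes in each direction; black marks and bars give the mean and SD of 3 replicates. SNZ1 and ARG1 lie highest, at 5.23 and 4.83, PHO12 and PHO11 lowest, and GCN2 spans 0.

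Targets of the activator Gcn4, the comparison closest to Gcn2 itself, stood above other genes as a list at the preset correlation (cameraPR adjusted p = 3.0e-34). The list did not pass with an estimated correlation (adjusted p = 0.389). Of 64 members, 16 rose, none fell and 48 did not pass, while 35 rose and 4 fell when adjusted over the list alone. The median member was at 0.84 on replicate 1, 0.94 on replicate 3 and 0.67 on replicates 2 and 4, a mean of 0.82 ± 0.14 (SD, n = 3). The exact sign-flip p was 0.25, the smallest it can be. SNZ1 and ARG1 had the smallest p-values. The 4 that fell over the list alone were ADE1 at -0.98, ADE4 at -0.83, BAT2 at -0.97 and LEU3 at -1.01, which belong to purine and branched-chain synthesis and its regulation. With replicates 2 and 4 turned, the mean of replicate medians was 0.37.

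Within these pathways the arginine list, all of whose genes are also in the Gcn4 target list, had the largest mean of medians. Of 9 arginine synthesis genes 6 rose and none fell (8 and 0 when adjusted over the list alone), with a mean of replicate medians of 2.48 ± 0.07 (SD, n = 3; cameraPR adjusted p = 5.7e-42, and adjusted p = 0.340 with an estimated correlation). ARG1 and ARG4, given above, were among those that rose. With replicates 2 and 4 turned the arginine list's mean log2 ratio went from 2.36 to 0.83 and it did not pass (adjusted p = 0.128). Of 22 methionine and sulfur assimilation genes 7 rose and none fell (9 and 1 over the list alone), with a mean median of 0.70 ± 0.20 (cameraPR adjusted p = 1.4e-10, and adjusted p = 0.389 with an estimated correlation). MET13, a methylenetetrahydrofolate reductase, rose by 1.92 ± 0.08 and MET16, of sulfate reduction, by 1.84 ± 0.16, beside STR3.

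Smaller amino acid lists also stood above other genes at the preset correlation. Of 9 lysine genes LYS1 and LYS2 rose, by 1.74 ± 0.09 and 1.34 ± 0.34, and LYS14 was at 0.88 (mean of medians 0.50 ± 0.09; 3 rose over the list alone; cameraPR adjusted p = 4.8e-05, and adjusted p = 0.389 with an estimated correlation). Of 13 aromatic amino acid genes only TRP5 rose, by 1.20 ± 0.19, with ARO1 at 1.09 and TRP2 at 1.04 (mean of medians 0.84 ± 0.10; 8 rose over the list alone; adjusted p = 2.6e-06, and adjusted p = 0.389 with an estimated correlation). Of 7 histidine genes HIS3 rose, by 1.44 ± 0.31, with HIS5 and HIS7 at 0.90 each (mean of medians 0.69 ± 0.30; 4 rose over the list alone; adjusted p = 0.0042, and adjusted p = 0.389 with an estimated correlation). Without replicate 3 the limma adjusted p was 0.169 for LYS2, 0.221 for TRP5 and 0.149 for HIS3, and without replicate 1 it was 0.0925, 0.107 and 0.0545. Without replicate 2 alone LYS2 and TRP5 were at 0.0555 and 0.0535. LYS14, ARO1, TRP2 and HIS7 passed without replicates 2 and 4 (adjusted p = 0.0397, 0.0367, 0.0482 and 0.0319).

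The branched-chain amino acid list passed with no single gene past limma. None of its 10 genes passed limma over all genes, 5 passed at an unadjusted p under 0.05, 3 were higher by SAM on 3 replicates, and 3 rose and 1 fell over the list alone. ILV6 stood at 1.29, LEU4 at 1.03 and BAT2 at -0.97, and without replicates 2 and 4 ILV6 and LEU4 passed (adjusted p = 0.0233 and 0.0444). The list's mean of medians was 0.47 ± 0.21 (SD, n = 3; cameraPR adjusted p = 0.0212, and adjusted p = 0.477 with an estimated correlation), and its adjusted p was 0.0840 without replicate 1, 0.0870 without replicate 3 and 0.0795 with a dye term. The 19 genes of serine, glycine, threonine, glutamate, proline and asparagine synthesis did not pass as a list (mean of medians 0.17 ± 0.22; cameraPR adjusted p = 0.0631). That list's adjusted p was 0.0175 without replicates 2 and 4, 0.0289 after scaling and 0.0276 with replicates 2 and 4 turned. Among 22 amino acid and nitrogen permease genes, MEP1, an ammonium permease, rose by 1.27 and DIP5, a permease for acidic amino acids, fell by 1.90, and the list did not pass (adjusted p = 0.954).

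Purine synthesis genes were lower. Of 15 genes ADE17 and ADE13, which act late in the pathway, fell by 1.87 and 1.35, none rose, and 7 fell over the list alone, with ADE1 at -0.98. The mean of medians was -0.42 ± 0.31 (SD, n = 3; cameraPR adjusted p = 4.7e-04, and adjusted p = 0.477 with an estimated correlation), and the list's mean log2 ratio was -0.0025 with replicates 2 and 4 turned (adjusted p = 0.828). Without replicate 3 the ADE13 adjusted p was 0.135. The phosphate regulon was the lowest list: 6 of 16 genes fell, none rose and 11 fell over the list alone. They were PHO11, PHO12, VTC3, VTC1, the transporter PHO84 at -1.49 and VTC4 at -1.46. The mean of medians was -1.18 ± 0.21 (cameraPR adjusted p = 9.7e-24, and adjusted p = 0.340 with an estimated correlation). With replicates 2 and 4 turned the phosphate list's mean log2 ratio went from -1.55 to -0.50 and it did not pass (adjusted p = 0.128). Of 22 iron regulon genes SIT1 fell and none rose (6 fell and 1 rose over the list alone), with FET3 and FTR1, of high-affinity iron uptake, at -1.27 and -1.18 (mean of medians -0.45 ± 0.09; adjusted p = 1.1e-04, and adjusted p = 0.389 with an estimated correlation). FET3 passed without replicate 1 (adjusted p = 0.0416), and FET3 and FTR1 without replicates 2 and 4 (adjusted p = 0.0424 and 0.0246).

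**Figure D3:**
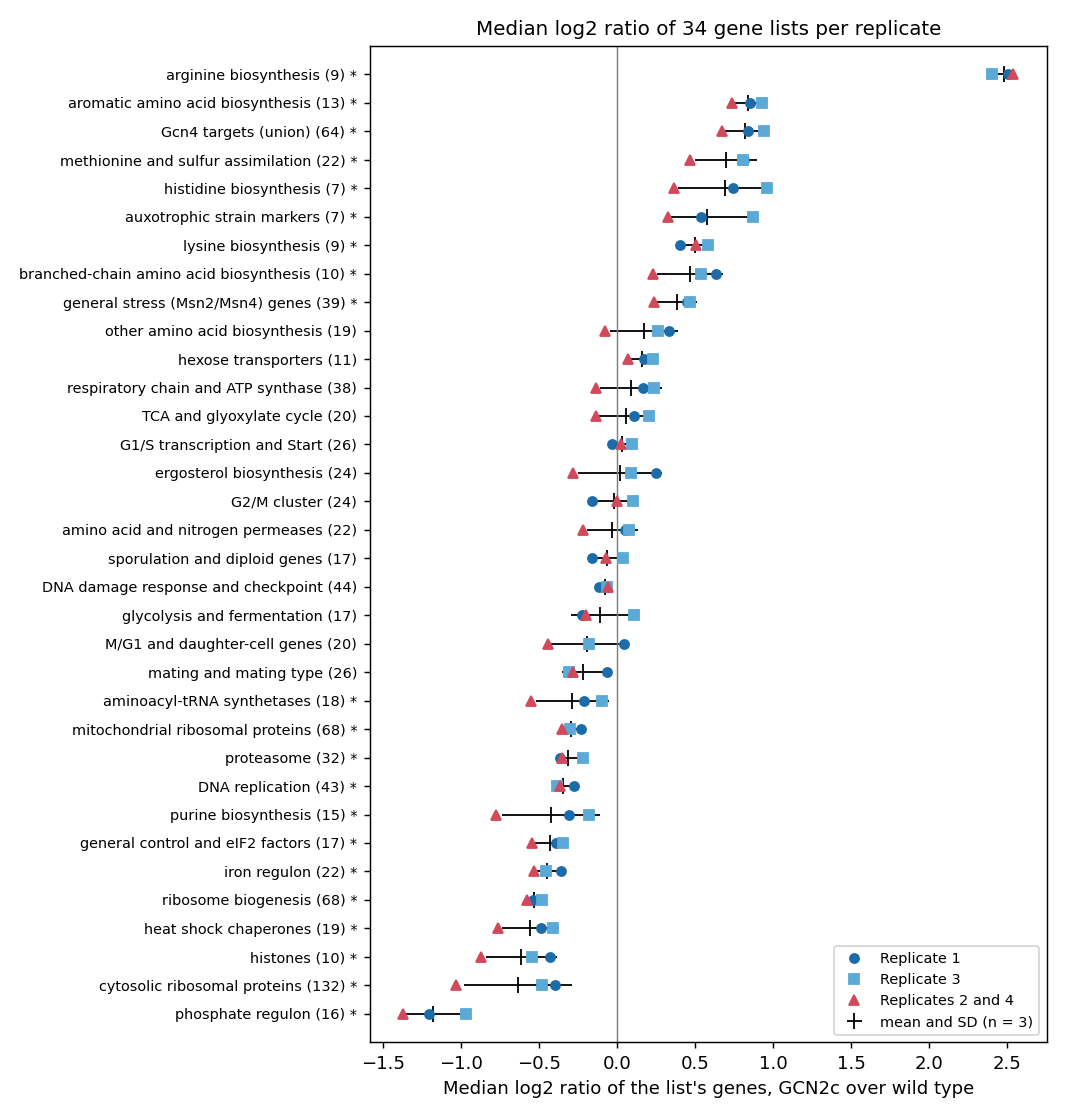
Median log2 ratio of GCN2c over wild type over the tested genes of each of 34 lists, per replicate, with the mean and SD of 3 replicates in black; gene numbers are in brackets and stars mark the 21 lists past a cameraPR adjusted p of 0.05. Arginine synthesis lies highest at 2.48 and the phosphate regulon lowest at -1.18, and cytosolic ribosomal proteins lie lower on replicates 2 and 4 (-1.03) than on replicates 1 and 3.

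Translation genes were lower as lists, with small changes per gene. None of 132 cytosolic ribosomal protein genes passed limma over all genes (84 at an unadjusted p under 0.05, 0 by SAM on 3 replicates), yet all 132 had a negative log2 ratio and 48 fell over the list alone. Many of the 132 are A and B copies, and copies of near-identical sequence can share signal. The median gene was at -0.40 on replicate 1, -0.48 on replicate 3 and -1.03 on replicates 2 and 4, a mean of -0.64 ± 0.34 (SD, n = 3; cameraPR adjusted p = 7.8e-19, and adjusted p = 0.430 with an estimated correlation). RPS29B stood at -1.06 and RPL9A at -1.18, and RPL20B at -0.96 and -1.02 on replicates 1 and 3 and -1.03 on replicates 2 and 4. RPL9A passed without replicate 1 (adjusted p = 0.0454), and RPS29B and RPL20B without replicates 2 and 4 (adjusted p = 0.0404 and 0.0452). The list's mean log2 ratio was 0.0048 with replicates 2 and 4 turned (adjusted p = 0.923). Of 68 ribosome biogenesis genes none passed limma over all genes (39 at an unadjusted p under 0.05, 0 by SAM on 3 replicates), while 22 fell and 1 rose over the list alone. Their mean of medians was -0.53 ± 0.05 (cameraPR adjusted p = 6.0e-10, and adjusted p = 0.340 with an estimated correlation). BRX1 and NOP7, of the large subunit, stood at -0.90 and -0.86, and NOP1, the rRNA methyltransferase fibrillarin, at 0.91 (adjusted p = 0.0965, and 0.0465 without replicates 2 and 4).

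Other parts of the translation machinery showed weaker shifts. The 17 general control and eIF2 factor genes had a mean of medians of -0.43 ± 0.10 (SD, n = 3; cameraPR adjusted p = 0.0202, and adjusted p = 0.389 with an estimated correlation). None passed limma over all genes or over the list alone (6 at an unadjusted p under 0.05, 0 by SAM on 3 replicates), and GCN20 stood at -0.67 and GCD7 at -0.64. The 68 mitochondrial ribosomal protein genes were at -0.30 ± 0.06 (adjusted p = 0.0202, and adjusted p = 0.430 with an estimated correlation). Among them only MRPL39 passed, and it rose, by 1.98 ± 0.25, with MRPL13 at 1.22 and MRPL1 at -0.59. The 18 aminoacyl-tRNA synthetase genes were at -0.29 ± 0.24 (adjusted p = 0.0264, and adjusted p = 0.607 with an estimated correlation), with MES1 at -0.96, SES1 at -0.86 and GLN4 at -0.84. None of the 18 passed limma over all genes (6 at an unadjusted p under 0.05, 0 by SAM on 3 replicates), and 4 fell over the list alone, while MES1 had an adjusted p of 0.0426 without replicates 2 and 4. The synthetase list had an adjusted p of 0.0659 without replicate 1 and 0.162 without replicates 2 and 4, and its mean log2 ratio was 0.014 with replicates 2 and 4 turned (adjusted p = 0.813).

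The series title names a G1/S checkpoint after DNA damage. No treatment is named for these cultures, so the cell cycle lists bear on growing cells and not on that checkpoint. The 26 genes of G1/S transcription and Start showed no shift as a list: the median member was at -0.03, 0.09 and 0.03 on replicate 1, replicate 3, and replicates 2 and 4 (mean 0.03 ± 0.06, SD, n = 3; exact sign-flip p = 0.75, where 0.25 is the smallest possible). The list's median of fitted ratios had the other sign, at -0.02, and 13 genes lay on each side of 0 (cameraPR adjusted p = 0.753). PCL1, a cyclin of the Pho85 kinase expressed in G1, was the 1 member that rose, by 1.36 ± 0.13 (limma adjusted p = 0.0330, and 0.135 without replicate 3). The G1 cyclin gene CLN1 stood at 0.74 ± 0.20 (adjusted p = 0.126). G2/M genes (24 tested, none past limma, 4 at an unadjusted p under 0.05, 1 higher by SAM on 3 replicates) and M/G1 genes (20 tested, the cell wall gene PIR1 rose by 1.96) did not pass as lists, with cameraPR adjusted p = 0.833 and 0.706.

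Genes of DNA synthesis were lower as lists and those of DNA repair were not shifted detectably. Of 43 DNA replication genes 37 had a negative ratio, 28 of them on every replicate, and the mean of medians was -0.34 ± 0.06 (SD, n = 3; cameraPR adjusted p = 4.7e-04, and adjusted p = 0.389 with an estimated correlation). None passed limma over all genes or over the list alone (11 at an unadjusted p under 0.05, 0 by SAM on 3 replicates). RNR1, the large subunit of ribonucleotide reductase, stood at -0.98 ± 0.19 (adjusted p = 0.0727), the polymerase alpha subunit gene POL12 at -0.76 and POL30, the sliding clamp PCNA, at -0.74. All 10 histone genes had a negative ratio (mean of medians -0.62 ± 0.23; adjusted p = 0.0012, and adjusted p = 0.477 with an estimated correlation). None of the 10 passed limma over all genes (7 at an unadjusted p under 0.05, 0 by SAM on 3 replicates) and 7 fell over the list alone, with HTA2 at -0.83, HHF1 at -0.81 and HHF2 at -0.64. Histone genes of near-identical sequence can share signal. The 44 DNA damage response and checkpoint genes had a mean of medians of -0.08 ± 0.03 (adjusted p = 0.753). None of these passed limma (6 at an unadjusted p under 0.05, 0 by SAM on 3 replicates), and the smallest p-values were those of the repair genes MSH6 at -0.84 (adjusted p = 0.104) and OGG1 at -0.74 (adjusted p = 0.131).

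Stress and protein folding genes moved in different ways. General stress genes of the Msn2 and Msn4 activators stood above other genes: of 39, TFS1 rose by 1.60 ± 0.19 and the polyubiquitin gene UBI4 by 1.36 ± 0.17, none fell, and 14 rose over the list alone, with YGP1 at 1.09 (mean of medians 0.38 ± 0.13, SD, n = 3; cameraPR adjusted p = 1.9e-05, and adjusted p = 0.389 with an estimated correlation). Without replicates 1 and 3 in turn, UBI4 had an adjusted p of 0.0634 and 0.131. Heat shock chaperone genes stood below other genes: 17 of 19 had a negative ratio and 11 fell over the list alone, with SSA1 at -1.12 and SSA2 at -1.08 (mean of medians -0.56 ± 0.18; adjusted p = 1.2e-04, and adjusted p = 0.477 with an estimated correlation). SSA1 and SSA2 are near-identical and can share signal. Without replicates 2 and 4, YGP1, SSA1 and SSA2 passed (adjusted p = 0.0367, 0.0404 and 0.0457). The 1 member that passed, the ribosome-associated chaperone gene SSB1, rose by 1.58 ± 0.37 (adjusted p = 0.0361, and 0.0666 without replicate 3), while its near-identical copy SSB2, named after its value was seen, stood at -0.89. Probe sequences were not available, so whether the SSB1 spot measures SSB1 was not checked. All 32 proteasome genes had a negative ratio (mean of medians -0.31 ± 0.08; adjusted p = 0.0082, 0.0555 without replicate 1, and adjusted p = 0.389 with an estimated correlation). None passed limma over all genes or over the list alone (3 at an unadjusted p under 0.05, 0 by SAM on 3 replicates), with PRE1 at -0.63, RPT1 at -0.57 and PRE3 at -0.44.

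Central metabolism lists did not pass, and the glycolysis list cannot be read. Of its 17 genes 6 (TDH2, TDH3, FBA1, PDC1, PGK1 and ENO1) lay on at least 2 of the 3 replicates within 0.005 of the ratio that the most genes shared on that array. That ratio was -0.23 on replicate 1, which was also the list's median there, and 0.22 on replicate 3. The list had a cameraPR adjusted p of 0.284, and of 0.120 over the 11 genes tested once such values were set to missing. The mean of medians was 0.09 ± 0.20 (SD, n = 3) for 38 respiratory chain and ATP synthase genes and 0.06 ± 0.18 for 20 genes of the TCA and glyoxylate cycles. It was 0.16 ± 0.08 for 11 hexose transporter genes and 0.02 ± 0.27 for 24 ergosterol genes. Their cameraPR adjusted p-values were 0.280, 0.923, 0.923 and 0.809. The respiratory list had an adjusted p of 0.0464 without replicates 2 and 4. With replicates 2 and 4 turned, the respiratory and ergosterol lists each had an adjusted p of 0.0276.

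Markers of strain and cell type were measured beside these lists. Of 7 auxotrophic marker genes tested HIS3 and LYS2 rose, as above, and both also belong to amino acid lists, while ADE2 stood at -0.85 (mean of medians 0.58 ± 0.27, SD, n = 3; cameraPR adjusted p = 0.0455, 0.171 without replicate 3, and adjusted p = 0.477 with an estimated correlation). The 26 mating genes did not pass as a list (adjusted p = 0.177, and 0.0494 without replicates 2 and 4), nor did the 17 sporulation genes (adjusted p = 0.803). Among the mating genes MF(ALPHA)1, an alpha-factor gene singled out after its values were seen, stood at 4.93 on replicates 2 and 4 and at -0.92 and -1.42 on replicates 1 and 3.

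Of the 34 lists, 21 passed a cameraPR adjusted p of 0.05, 9 above and 12 below other genes. Lists share genes: all arginine and histidine genes, and most lysine genes, are also in the Gcn4 target list. The 21 are thus not separate results. None held with an estimated correlation, where 3 replicates leave little power. Among the 21 that estimate ran from -0.03 (general control and eIF2 factors) to 0.63 (histones). It was 0.51 for cytosolic ribosomal proteins and 0.07 for arginine synthesis, against the preset 0.01. Where genes vary together more than the preset, the cameraPR p-values are too small. By fry, which asks whether a list's genes move one way without setting them against other genes, 7 passed. At an unadjusted cameraPR p under 0.05, 22 passed. With replicates 2 and 4 turned 7 passed, 3 others and 4 of the 21: Gcn4 targets, methionine and sulfur assimilation, branched-chain synthesis and general stress genes. The 3 others were the serine to asparagine synthesis, respiratory chain and ATP synthase, and ergosterol lists (adjusted p = 0.0276 each). Of the other 17 lists, 16 passed without replicates 2 and 4.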

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

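Tests chosen only after the result was seen were the 4 columns taken as 4 replicates, SAM on 3 replicates, values beyond 16 or at the ratio many genes share set to missing, and only names matched to the R64 table. The count of 126 changed genes was 152 after centring, 103 after scaling, 116 for genes with values on at least 2 arrays, 147 with values beyond 16 set to missing, 127 with values at the shared ratio set to missing and 183 with matched names only. It moved further to 191 with genes on all 4 arrays, 201 with a robust variance prior, 277 at an adjusted p under 0.10 and 650 with a dye term, and without each replicate in turn it ran from 74 to 353. It was 1062 with the 4 columns as 4 replicates. One-class SAM, which the design text names, called 1398 genes at a false discovery rate under 0.05 and 1948 under 0.10 on the 4 columns, and 212 and 359 on 3 replicates. Counting the nearly identical columns apart adds a replicate with almost no spread. A plain t-test on the 5997 genes with all 3 values gave 954 at an unadjusted p under 0.05 and 0 after Benjamini-Hochberg, where limma gave 1268 and 126 over 6130 genes, 1244 and 124 of them among the 5997. All 126 calls were kept with centring, the dye term, the robust prior and the 4 columns, and 66 without replicate 3. The dye term fits the hybridisation of replicates 2 and 4 exactly, so it absorbs any deviation of that hybridisation, from dye or otherwise. Calls kept with the dye term or the 4 columns are therefore weak evidence that they hold. Higher genes made up 84.1% of calls, against 55.8% with a dye term and 44.4% with the 4 columns; centring gave 86.8% and scaling 83.5%.

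Turning replicates 2 and 4 left 0 changed genes by limma (250 at an unadjusted p under 0.05) and 7 lists, 4 of the 21 and 3 that had not passed before. It put the GCN2 log2 ratio at 0.13 and the mean of replicate medians (median log2 ratio of the Gcn4 target list) at 0.37, and gave list means of 0.0048 for cytosolic ribosomal proteins, -0.0025 for purine synthesis and 0.014 for aminoacyl-tRNA synthetases, each list on the other side of the remaining genes from before. Turning sets one dye orientation against the other by construction. Of the 21 lists, 0 passed with an estimated correlation and 7 with fry, and 17 passed under each of the other 15 settings. The 4 that did not were auxotrophic markers (adjusted p from 0.024 to 0.171), branched-chain synthesis (0.0032 to 0.087), aminoacyl-tRNA synthetases (0.0127 to 0.162) and the proteasome (0.006 to 0.0555), and the cause was not tested. Of 34 named genes past the threshold, 26 passed under the same 15 settings and 8 (ADE13, HIS3, LYS2, PCL1, PLB2, SSB1, TRP5 and UBI4) did not under at least 1. Other named genes gained a call, 30 with the dye term and 40 with the 4 columns. The lowest limma adjusted p over the 15 settings, which include the dye term and the 4 columns, was 0.0448 for GCN4 and 0.01 for RNR1. Over the fits that left out replicates, the lowest was 0.0937 for GCN4 and 0.0588 for RNR1. Without each replicate in turn, the mean of replicate medians stayed between -0.0025 and 0.06 for the G1/S list and between 0.76 and 0.89 for the Gcn4 list. Testing each row of a gene apart was not run, since each gene had 1 row. Signal over background could not be weighed without spot intensities.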

Other observations

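Tests chosen only after the result was seen were those on the near identity of replicates 2 and 4, on the alpha-specific genes, and on whether the cell wall genes were picked for being high; the cell wall list itself was drawn up after 7 of its genes had been seen. Of the 126 changed genes, 88 lay in none of the 34 lists, 78 higher and 10 lower. Several belong to cell wall synthesis and the cell integrity pathway. SLT2, its MAP kinase, rose by 2.31 ± 0.10 (SD, n = 3; limma adjusted p = 0.0089) and KDX1, a related kinase gene, by 2.73 ± 0.99 (adjusted p = 0.0391). Of 21 genes of this pathway 9 rose and none fell, but 5 of the 9 were among the 7 seen beforehand. Of the 14 others 4 rose, with a mean of replicate medians of 1.09 ± 0.13. The 5 were SLT2, KDX1, GSC2, NCW2 and YPS3, and the 4 were the transglycosylase gene CRH1 at 1.74, PRM5 at 1.31, DFG5 at 1.35 and PIR1 at 1.96. PIR3 stood at 0.48 and CWP1 at -0.30.

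Outside that pathway, and named after their values were seen, genes of mitochondrial transport rose: ORT1, the ornithine carrier, by 2.23 ± 0.44, ODC2, an oxodicarboxylate carrier, by 1.89 ± 0.40 and GGC1, the guanine nucleotide carrier, by 2.23 ± 0.32 (SD, n = 3; limma adjusted p between 0.0144 and 0.0249). BNA2, of NAD synthesis from tryptophan, rose by 1.90 ± 0.36, beside BNA1 at 2.34. HAC1, the transcription factor of the unfolded protein response, rose by 1.58 ± 0.38. The peroxiredoxin gene AHP1 stood at -1.48 ± 0.18 and the aldehyde dehydrogenase gene ALD6 at -1.37 ± 0.24, while ALD5 rose by 1.54 ± 0.31. These groups were not tested as lists.

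The cell wall genes were weighed on the 14 members counted as not seen when the list was drawn up. The 14 include PIR1, which is also in the M/G1 list fixed beforehand, as are PIR3 and CWP1, counted as seen. The median of the 14 lay above that of all genes on 3 of 3 replicates. It was at 1.15, 1.18 and 0.93 on replicate 1, replicate 3, and replicates 2 and 4. The shift of these genes was thus not confined to a single hybridisation. The pathway was noticed largely through genes past the threshold, which all had one sign on every replicate. This outcome was therefore likely beforehand and is weak evidence. Coding length is argued against: random lists matched on it had a typical median of -0.02. Over genes, ratio and length were barely related (Spearman rho = 0.024). The median of the 14 lay at the 100th percentile of the 10000 random lists. That rank is overstated, since genes were drawn independently and the pathway was chosen for high members. On selection of high genes, the 14 had a cameraPR p of 6.5e-12 at the preset correlation. With an estimated correlation of 0.290 between them, camera gave p = 0.0837. These values cannot decide on selection, since the pathway was chosen for high members in the same ratios. A candidate explanation is that cell integrity signalling is more active in the strain labelled GCN2c, if the ratios run in the direction assumed. It is a hypothesis drawn from the same ratios. The tests bear on the position of the list and not on signalling, which was not measured. Phosphorylated Slt2 in both strains would test it, and the strain background is left open.

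Replicates 2 and 4 may be 1 hybridisation deposited under both names: 97.46% of genes lay within 0.01 log2 of one constant difference. Separate cultures that vary as replicates 1 and 3 do are argued against, since the SD of the differences was 7.48% of theirs. Whether the same slide was scanned or scaled again was not tested, and no biological explanation was tested.

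On replicates 2 and 4 the alpha-specific genes had a median of 2.72, against -0.37 on replicate 1 and -0.84 on replicate 3, while 6 a-specific genes had medians of -0.41, -0.36 and -0.33. Of 10000 random lists of 4 genes matched on the spread between replicates 1 and 3, 0.04% reached that median. This excludes nothing, since the genes were singled out for these values and STE3 has no value on replicate 3 to match on, so widely varying spots stay open. Alpha cells among those labelled GCN2c on that hybridisation may be the source, with 3 of 4 genes above the 95th percentile there of 1.31: MF(ALPHA)1 at 4.93, STE3 at 3.76 and MF(ALPHA)2 at 1.69. SAG1, the alpha-agglutinin gene, was at 0.07, and a-specific genes were not correspondingly lower, so this too stays open, as does a difference in strain between cultures. LEU2, a strain marker with no value on replicates 1 and 3, stood at 6.09 on replicate 4, and HKR1 had the same value there, so it is not read as a ratio of LEU2.

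The count of 126 changed genes was also taken with the sign of each replicate turned. Of the 4 sign patterns that 3 replicates allow, leaving aside a turn of all replicates together, 1 gave as many genes, the real one, and the highest other gave 0 by limma. These patterns are too few for a share under 0.05.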
